A study of Mus musculus with 18 samples.

How the data were processed

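Messenger RNA was measured on 2-colour oligonucleotide arrays from Agilent, per the file headers and labels, in 9 RNA samples: 2 normal mammary glands, 2 NIC tumour pools of 5 tumours each, and 5 single ErbB2 knock-in (KI) tumours. Per the labels' protocols, total RNA was extracted with a column kit, passed through a single round of linear amplification, and coupled to Cy3 or Cy5. Every RNA was set against a commercial mouse reference RNA on 2 arrays with the dyes exchanged, which gave 18 arrays of 43790 spots.

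The deposited value tables hold log2 ratios of sample over reference, 1 column per array. The normal and NIC arrays lie together in a single table, and the KI arrays have a table of their own. The 2 tables also belong to different platform records, per the file names. Both are numbered by spot, and the probe at each spot was read from the KI scanner files and taken to be the same for the normal and NIC arrays. Genes joined this way correlated between KI and NIC samples at r = 0.621 to 0.791, where a different spot layout would give values near 0. For the KI table the scale and direction were found by setting each column against the scanner values of the same array (Pearson r over spots between 0.982 and 0.988 after loess, the column turned to sample over reference). For the normal and NIC table they were taken by analogy, since no scanner values of those arrays were used here. The tables' column medians lay between −0.0099 and 0.026. The submitters' processing notes name RMA, with no role given, and other steps behind the tables are not given in the sources used here. Interquartile ranges differed between columns (0.422 to 0.562 for KI, 0.514 to 0.970 for the other arrays), so the columns were not forced to share 1 distribution. On 7 KI arrays the labelling protocols name the opposite dyes from the label fields. The label fields were followed, since all columns correlate above 0 in the value table.

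Scanner files of the 10 KI arrays were used as well. They hold spot and background intensities per channel, written by Agilent Feature Extraction A.7.5.1 per the file headers, and a log10 ratio of Cy5 over Cy3 that the software computed from spatially detrended and dye-normalized signals, per the file headers. Here the intensities were background corrected with limma's normexp (offset 50) and normalized within each array by loess, with control spots at weight 0 and spots marked as outliers (0.29%) left out. Image extraction took place on 2 days, with 2 KI arrays on the smaller one, each of them partner to an array of the other day. Scan days of the remaining arrays were not used here.

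All 2256 control spots were left out, and the 41174 different probes were reduced to 28919 genes or unnamed transcripts, each represented by its probe with the highest mean signal on the KI arrays. Probes were named by accession (20716), by current symbol (5039) or by an older symbol (5279) through a RefSeq gene table of assembly GRCm38.p6, and 10140 kept the name in the file. That table also gave the order of genes along chromosomes, and no coordinate of it is printed. Among named genes with several probes, the probes differed by more than 1 log2 unit for 27 of 34 in NIC against normal, 28 of 36 in KI against normal, and 14 of 20 in KI against NIC. For Lgals7 they lay more than 1 log2 unit to either side of 0. Smaller opposite values and probes near 0 occurred for other genes and are given in the comparisons.

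The replicate was the RNA sample, the mean of its dye pair. Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all 28919 genes, and a gene was called at an adjusted p under 0.05. NIC against normal was fitted on its own 4 RNA samples. KI against normal and KI against NIC came from 1 fit of all 9 RNA samples. In that fit NIC pools and single KI tumours share 1 estimate of the spread, although a pool averages over its tumours. Values were handled with the data.table package (version 1.17.8). Labels give an identifier for each gland, pool and tumour but say nothing of litters or of more than 1 sample per animal, so p-values measure the spread between these RNA samples. The number of RNA samples limits the precision.

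KI against normal and KI against NIC cross the 2 tables, and table, platform record and KI group cannot be told apart. The condition set for testing across tables before the data were examined was that KI columns follow from their own scanner values at r over 0.95 and that medians and spreads of the tables overlap. Medians overlapped, and interquartile ranges did so through the NIC columns alone (0.514 to 0.559). Those of the normal columns (0.761 to 0.970) lay above those of all KI columns (0.422 to 0.562). The column SDs did not overlap (0.726 to 0.858 for KI, 0.910 to 1.18 for the others). The condition was counted as met, a choice made after seeing both measures, and a fit with all arrays scaled to 1 spread was added for that reason.

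20 gene lists were fixed before the data were examined: Wnt/β-catenin targets and feedback, Wnt pathway components, ErbB receptors, ligands and feedback, Erbb2 neighbours on chromosome 11, proliferation, luminal epithelium, basal and myoepithelial, milk proteins and lactation, adipocyte, brown fat, skeletal muscle, B and T lymphocyte, myeloid and macrophage, endothelium, fibroblast and matrix, EMT regulators (epithelial-mesenchymal transition), tight and adherens junction, hypoxia and glycolysis, interferon response, and peripheral nerve. Some genes stand in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists. A call lost in the second run need not come from correlation. In NIC against normal the junction list's estimate of −0.011 was under the preset, yet its unadjusted camera p rose from 4.64e-09 to 0.0229.

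Genes were named by a rule fixed before the data were examined. It names Erbb2, Ctnnb1, Cdh1 and Axin2 in each comparison, and the 10 largest rises and 10 largest falls among called genes whose groups overlap on no array. Of each list it names up to 4 called members with the largest differences, or up to 2 where none was called. For the KI tumours it names the 10 genes with the largest range. Symbols ending in Rik or made of Gm or LOC and digits were left out. Genes outside the rule are said to be so where they appear.

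For the spread between KI tumours, a gene counted if its range over the 5 tumours in the loess-normalized scanner values exceeded 2 log2 units and also 3 times the median difference between the arrays of a dye pair. A probe saturated on all KI arrays, or not well above background on any, has only a bound there, which held for 13 and 183 genes. The background flag passed 95.2% to 98.8% of spots in the sample channel of the KI arrays, so it marks few dim probes. No fold is given for a gene saturated on all 10 KI arrays.

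On simulated data, with each gene's spread pooled over the 3 groups, 200 of 28919 genes were changed. In KI against normal 49% were recovered for a log2 change of 1 and 81% for a change of 2. In KI against NIC 55% and 82% were recovered. For NIC against normal 200 changed genes gave 0 calls, while with 7230 genes changed, 67.9% and 88.2% were recovered. The pooled spread includes the KI tumours, whereas the real fit of this comparison used glands and NIC pools alone. A shifted list was found in each comparison, and 0 of the 19 other lists were called. These lists held genes simulated to vary independently and were tested at the preset correlation. The result therefore says nothing of false calls in the real lists, whose estimated correlations reached 0.787 (interferon response, KI against normal). Alternatives covered centring and quantile normalization of the arrays, each dye orientation alone, all arrays with a dye term and the RNA sample as a random block, the mean of all probes, a filter on dim probes, a trended and robust prior, a minimum log2 difference of 1, the samples in the fit, scanner values for KI, and leaving out each RNA sample. The scaling to 1 spread and a filter to genes with a mean signal above the median were chosen after seeing the data. The signal is that of both channels on the KI arrays, so the filter can drop genes that are bright in normal gland alone. RMA was not rerun.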

Results

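The arrays measured gene expression in whole flash-frozen mammary tissue of female FVB/N mice, an inbred strain widely used for mammary tumour models. The 9 RNA samples fell into 3 groups: 2 normal mammary glands, 2 NIC tumour pools of 5 tumours each, and 5 single tumours from ErbB2 knock-in mice, called KI. ErbB2 is a receptor tyrosine kinase of the epidermal growth factor receptor family. The series title places these tumours in a study of β-catenin, an adhesion protein that also carries Wnt signals to the nucleus. Levels are log2 ratios of sample over a common reference RNA, the mean of 2 arrays per RNA sample, and the number of RNA samples limits the precision.

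Across the 28919 genes tested, the 2 NIC pools correlated with each other at r = 0.935, the 2 normal glands at 0.875, and single KI tumours with one another at 0.709 to 0.894. KI tumours correlated with NIC pools at 0.621 to 0.791 and tumours of either kind with normal glands at 0.385 to 0.50. These are correlations across genes, which are not independent replicates. A pool averages its 5 tumours, so the likeness of the 2 NIC pools does not show how single NIC tumours vary. As a median over its genes, the adipocyte list stood at 3.70 and 2.99 in the normal glands, at 0.43 and 0.28 in the NIC pools, and between 0.041 and 0.53 in the KI tumours.

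**Figure D1:**
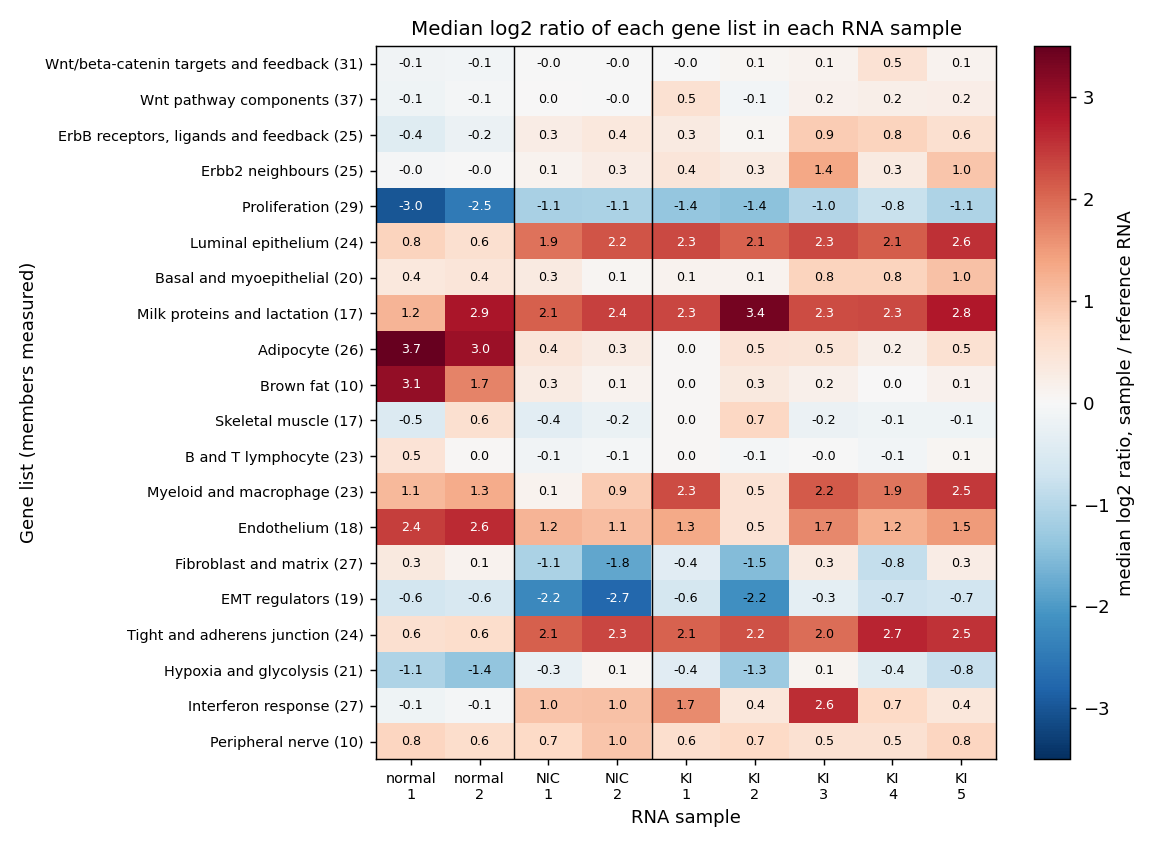
Heatmap of the median log2 ratio of sample over reference RNA for 20 gene lists (vertical axis, with the number of measured members) in the 9 RNA samples (horizontal axis; lines part normal, NIC and KI). The adipocyte list was at 3.70 and 2.99 in the normal glands and at 0.53 or lower in each of the 7 tumour samples.

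NIC tumours were compared with normal glands to describe how these tumours differ from the tissue they arise in. Of 29 proliferation genes 22 were higher in the NIC pools, of 24 junction genes 15 were higher, and of 26 adipocyte genes 15 were lower. The 3 lists lost their camera call with an estimated correlation (adjusted p = 0.337, 0.337 and 0.382 with an estimated correlation). For the junction list that estimate was −0.011, under the preset 0.01, so correlation among its genes was not what cost it the call. The mitotic kinase gene Aurkb was 11.5-fold higher (log2 difference 3.53 ± 0.49 SE, n = 2 and 2, adjusted p = 0.028), and Ocln, encoding the tight junction protein occludin, was 12.3-fold higher by the probe used (3.62 ± 0.18, adjusted p = 0.0085), while its other probe differed by 0.062. Cd36, the fatty acid transporter of fat cells, was 64.7-fold lower (−6.02 ± 0.12, adjusted p = 0.00775). Axin2, a feedback inhibitor that Wnt/β-catenin signalling itself induces, was 25.6-fold lower (−4.68 ± 0.14, adjusted p = 0.00775). In all, limma called 5377 of 28919 genes, 2542 higher and 2835 lower in the NIC pools. Of the 3664 that differed at least 2-fold, 1964 were higher and 1700 lower. Among genes above the median signal on the KI arrays 2066 were called higher and 1364 lower. That filter can drop genes that are bright in normal gland alone, so its balance of rises and falls is partly built in.

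Axin2 stood at 1.67 ± 0.20 (SD, n = 2) in the normal glands and at −3.01 ± 0.054 (n = 2) in the NIC pools. The latter SD is between pools of 5 tumours and not between single tumours. Of the 31 measured Wnt/β-catenin targets and feedback genes, 5 rose, 7 fell and 19 did not pass the test (9 rose and 7 fell when adjusted over the list alone). Besides Axin2, falls were seen for Apcdd1, an inhibitor of Wnt receptors (−5.21 ± 0.57), and for the Notch ligand gene Jag1 (−3.61 ± 0.12; its other probe differed by −0.17). Sox9, a transcription factor of progenitor cells, rose by 2.98 ± 0.46, with its 3 probes between 0.39 and 3.30. The list as a whole was not called (camera adjusted p = 0.966). In the same samples the median difference was −2.17 for the adipocyte list, −1.47 for the fibroblast list and −0.93 for the endothelium list. β-catenin itself, Ctnnb1, differed by 0.25 ± 0.21 and was not called (adjusted p = 0.445). It ran from 0.062 to 0.43 without each sample, and its other 2 probes differed by 1.24 and 1.42. Among the 37 Wnt pathway components 8 rose and 3 fell (12 and 8 adjusted over the list alone; camera adjusted p = 0.184). The coreceptor gene Lrp5 rose by 3.68 ± 0.32, Axin1 and Gsk3b, both of the β-catenin destruction complex, by 2.69 ± 0.33 and 2.49 ± 0.18, and the corepressor gene Tle2 by 2.12 ± 0.30.

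Erbb2 was 3.45-fold higher in the NIC pools (1.79 ± 0.20, adjusted p = 0.0202), and its other 2 probes differed by 1.82 and 0.39. ErbB receptors, ligands and feedback genes held 9 that rose and 2 that fell among 25 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00153). The ETS transcription factor genes Etv5 and Etv4 rose by 4.68 ± 0.17 and 3.14 ± 0.14, and Dusp6, a phosphatase that restrains ERK, by 3.30 ± 0.26. Areg, the growth factor amphiregulin, went the other way (−4.55 ± 0.14). Of 25 measured Erbb2 neighbours on chromosome 11, 5 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00865). They were Erbb2, the adaptor gene Grb7 (2.02 ± 0.26), the sterol transporter gene Stard3 (1.88 ± 0.20), the topoisomerase gene Top2a (2.88 ± 0.33, also a proliferation gene; its other probe differed by 0.24) and Pgap3 (1.26 ± 0.16), the last outside the naming rule and chosen after its values were seen. Neither list held its call with an estimated correlation (adjusted p = 0.382 with an estimated correlation for both).

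Among proliferation genes 22 of 29 rose and 0 fell (27 adjusted over the list alone; camera adjusted p = 6.65e-14, adjusted p = 0.337 with an estimated correlation). Besides Aurkb these included the kinase gene Melk (3.05 ± 0.15), the ubiquitin-conjugating enzyme gene Ube2c (3.0 ± 0.20) and the spindle gene Nusap1 (2.99 ± 0.22). Hypoxia and glycolysis genes rose in 5 of 21 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00473, adjusted p = 0.382 with an estimated correlation). The oxygen sensor gene Egln3 rose by 4.13 ± 0.23, the oxidoreductase gene Ero1a by 3.71 ± 0.31, the glucose transporter gene Slc2a1 by 2.30 ± 0.19. Pfkfb3, a regulator of glycolysis, fell (−3.03 ± 0.36).

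In the luminal epithelium list 12 rose and 3 fell among 24 (15 and 4 adjusted over the list alone; camera adjusted p = 7.88e-05, adjusted p = 0.382 with an estimated correlation). The adhesion molecule gene Epcam rose by 3.87 ± 0.54, the protease inhibitor gene Spint2 by 3.22 ± 0.10 and the membrane glycoprotein gene Prom1 by 2.98 ± 0.27, whereas Foxa1, a transcription factor of hormone-responsive cells, fell (−3.04 ± 0.30). Tight and adherens junction genes rose in 15 of 24 cases and fell in 0 (17 and 0 adjusted over the list alone; camera adjusted p = 3.09e-08, adjusted p = 0.337 with an estimated correlation). Ocln was joined by Cldn1, a claudin (3.57 ± 0.27), by the polarity gene Crb3 (2.93 ± 0.42) and by the splicing regulator gene Esrp1 (3.71 ± 0.25; its other probe differed by −0.18). Cdh1, encoding E-cadherin, was 1.43-fold higher (0.52 ± 0.10, adjusted p = 0.0482). It lost its call in 8 of 16 alternatives, among them each that left out 1 sample. Over all 16 alternatives, those of dye and scaling included, the difference ran from 0.28 to 0.82 (adjusted p up to 0.241). The basal and myoepithelial list held 2 that rose and 7 that fell among 20 (3 and 10 adjusted over the list alone; camera adjusted p = 0.103). Snai2, a repressor of epithelial genes, fell (−3.95 ± 0.17), as did the smooth muscle myosin gene Myh11 (−2.40 ± 0.24) and the hemidesmosome collagen gene Col17a1 (−2.21 ± 0.34). The galectin gene Lgals7 rose by 3.78 ± 0.42, but its other probe went the opposite way (−1.81). Milk proteins and lactation genes were mostly not called, with 1 that rose and 1 that fell among 17 (3 and 1 adjusted over the list alone; camera adjusted p = 0.948, upward although the list's median was −0.33 and its mean −0.018). These were Lalba, the α-lactalbumin gene (3.13 ± 0.26), and the secreted mucin gene Glycam1 (−4.60 ± 0.15).

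Adipocyte genes fell in 15 of 26 cases and rose in 0 (18 and 0 adjusted over the list alone; camera adjusted p = 3.09e-08, adjusted p = 0.382 with an estimated correlation). Among them were the insulin-responsive glucose transporter gene Slc2a4 (−5.16 ± 0.16), the leptin gene Lep (−4.51 ± 0.33) and Dgat2, an enzyme of triglyceride synthesis (−4.48 ± 0.38). Brown fat genes fell in 4 of 10 cases and rose in 0 (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0106, adjusted p = 0.461 with an estimated correlation). These were the uncoupling protein gene Ucp1 (−3.95 ± 0.24), Elovl3 (−3.71 ± 0.27), Cidea (−2.27 ± 0.29) and Cox8b (−1.85 ± 0.32). Fibroblast and matrix genes fell in 10 of 27 cases and rose in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 4.60e-05, adjusted p = 0.461 with an estimated correlation). They included the matrix proteoglycan gene Dcn (−4.70 ± 0.56, its other probe −0.23), Pdgfra (−3.82 ± 0.43), Dpt (−3.81 ± 0.15) and Fap (−3.44 ± 0.52). Endothelium genes fell in 7 of 18 cases and rose in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 0.000106, adjusted p = 0.382 with an estimated correlation). Lower genes were the receptor genes Tek (−3.16 ± 0.41) and Flt1 (−1.92 ± 0.17), Vwf (−2.45 ± 0.31) and Cdh5 (−1.56 ± 0.13). EMT regulators rose in 3 and fell in 7 of 19 cases (4 and 10 adjusted over the list alone; camera adjusted p = 0.0226, adjusted p = 0.382 with an estimated correlation). The transcription factor genes Twist1 (−3.82 ± 0.28) and Twist2 (−2.95 ± 0.34) fell, and Sox4 rose by 2.89 ± 0.19.

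B and T lymphocyte genes fell in 11 of 23 cases and rose in 0 (14 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.000356, adjusted p = 0.492 with an estimated correlation). Examples were the B cell genes Ms4a1 (−3.88 ± 0.56) and Cd79b (−3.84 ± 0.15), the B cell chemokine gene Cxcl13 (−3.65 ± 0.41) and Jchain (−3.27 ± 0.14). Myeloid and macrophage genes went both ways, with 3 that rose and 2 that fell among 23 (3 and 3 adjusted over the list alone; camera adjusted p = 0.423). The arginase gene Arg1 rose by 3.57 ± 0.53, the complement genes C1qa and C1qb by 2.03 ± 0.14 and 1.89 ± 0.17. The pan-leukocyte gene Ptprc fell (−3.18 ± 0.47). Interferon response genes rose in 7 and fell in 2 of 27 cases (9 and 6 adjusted over the list alone; camera adjusted p = 0.115). Irf7, a master transcription factor of that response, rose by 3.97 ± 0.10, Isg15 by 3.15 ± 0.48 and Ifit1 by 2.63 ± 0.27, while the chemokine gene Cxcl9 fell (−2.88 ± 0.16). Skeletal muscle genes rose in 0 and fell in 2 of 17 cases (0 and 2 adjusted over the list alone; camera adjusted p = 0.109). The fallen genes were Acta1 (−3.03 ± 0.49) and Des (−1.44 ± 0.11). Peripheral nerve genes rose in 3 and fell in 2 of 10 cases (4 and 2 adjusted over the list alone; camera adjusted p = 0.0861). Sox10, Ncmap and S100b rose by 2.21 ± 0.21, 1.85 ± 0.16 and 1.65 ± 0.23, and Pmp22 fell (−2.48 ± 0.24).

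The largest rises of single genes ran from 27.8-fold to 48.2-fold. They were Stac2, an adaptor of calcium channels (5.59 ± 0.18), the carbonic anhydrase gene Car12 (5.37 ± 0.17), the ubiquitin ligase gene Rnf128 (5.37 ± 0.29), Fetub (5.26 ± 0.86; 4.11 without NIC pool 2 and 6.41 without NIC pool 1), Ier3 (5.22 ± 0.40), the ETS factor gene Etv1 (5.06 ± 0.12), Bhlha15, a transcription factor of secretory cells (4.98 ± 0.40), Arfgef3 (4.92 ± 0.14), Cmas (4.89 ± 0.48) and Cnot6l (4.80 ± 0.32). The largest falls ran from 47.2-fold to 209-fold. They were the retinol-binding protein gene Rbp4 (−7.71 ± 0.43), Pdk4, which restrains pyruvate oxidation (−7.42 ± 0.11), the muscle myosin light chain gene Myl1 (−6.17 ± 0.35), Mmd (−6.16 ± 0.28), the glucocorticoid-activating enzyme gene Hsd11b1 (−6.12 ± 0.38), Cd36, the glycogen synthase gene Gys2 (−5.99 ± 0.20), the natural killer cell receptor gene Klra1 (−5.69 ± 0.52), the lipid droplet gene Plin4 (−5.61 ± 0.34) and the fructose transporter gene Slc2a5 (−5.56 ± 0.26). Slc2a5 stood at −0.015 and −0.133 in the NIC pools. A ratio near 0 may give only a bound on its fall, since signal levels of these arrays were not used. Other genes named above also had a probe that differed by less than 1 log2 unit: Vwf −0.001, Pdgfra −0.10, Nusap1 0.11, Pmp22 −0.29, Melk 0.30, Ptprc −0.34, Arfgef3 0.345, Flt1 0.36, Pfkfb3 −0.38, Cdh5 −0.56, Sox10 0.62 and Bhlha15 0.66. With 2 samples per group, leaving out NIC pool 1 or NIC pool 2 left limma with 0 calls, in the Wnt/β-catenin target list too, although 6400 and 6977 genes kept an unadjusted p under 0.05. With the Cy3-labelled samples alone 2048 genes were called (6 in the Wnt/β-catenin target list), with all arrays and the RNA sample as a random block 9992 (19 in the list), and with all 9 samples in the fit 10395. Without either NIC pool none of the 95 called genes named here kept its call, though the difference of Axin2 was −4.64 without pool 1 and −4.72 without pool 2. Of the 95, 57 kept their call in every alternative that left out no sample.

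KI tumours were compared with normal glands across the 2 value tables, so a difference between tables enters every value below. Erbb2 was 3.77-fold higher in the KI tumours (log2 difference 1.91 ± 0.20 SE, n = 5 and 2, adjusted p = 0.000468), and its other 2 probes differed by 3.58 and 0.36. Stard3 and Pgap3, genes beside Erbb2, were 16.7-fold and 12.5-fold higher (4.06 ± 0.67, adjusted p = 0.00276, and 3.64 ± 0.54, adjusted p = 0.00176), and Stard3 was saturated on 2 of the 10 KI arrays. The growth regulator gene Myc was 10.2-fold higher (3.36 ± 0.55, adjusted p = 0.00264; its other 2 probes differed by 2.92 and 0.56). Cd36 of fat cells was again lower, by 74.0-fold (−6.21 ± 0.89, adjusted p = 0.00159). In all, 12349 of 28919 genes were called, 5158 higher and 7191 lower in KI tumours. Of the 4288 that differed at least 2-fold, 2647 were higher and 1641 lower. Among genes above the median signal on the KI arrays, a filter that favours genes bright in KI tumours, 3597 were called higher and 2908 lower.

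Axin2 was at 0.77 ± 1.77 (SD, n = 5) in the KI tumours, with single tumours from −1.61 to 2.52, and did not differ from the normal glands beyond that spread (−0.90 ± 1.09 SE, adjusted p = 0.544; −0.30 without KI tumour 1 and −0.57 without KI tumour 3). Of the 31 Wnt/β-catenin targets and feedback genes 9 rose, 2 fell and 20 did not pass the test (8 and 2 adjusted over the list alone; camera adjusted p = 0.0596). Myc was joined by Nkd2, a feedback inhibitor of Wnt signalling (2.83 ± 0.51), by the adhesion receptor gene Cd44 (2.29 ± 0.66) and by Sox9 (2.25 ± 0.32). Ctnnb1 was not called (0.59 ± 0.41, adjusted p = 0.282), and its other 2 probes differed by 1.52 and 0.89. Without KI tumour 3 it differed by 0.37, and as the mean of its probes by 1.0 (adjusted p = 0.0499; up to 0.616 over the alternatives). Wnt pathway components rose in 12 and fell in 3 of 37 cases (12 and 4 adjusted over the list alone; camera adjusted p = 0.0246, adjusted p = 0.430 with an estimated correlation). Lrp5, Axin1 and Gsk3b rose by 2.57 ± 0.23, 2.5 ± 0.25 and 2.13 ± 0.18, and the Wnt receptor gene Fzd4 fell (−1.96 ± 0.22). In the same samples the adipocyte list stood at a median difference of −2.33, the fibroblast list at −0.67 and the endothelium list at −0.80.

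**Figure D2:**
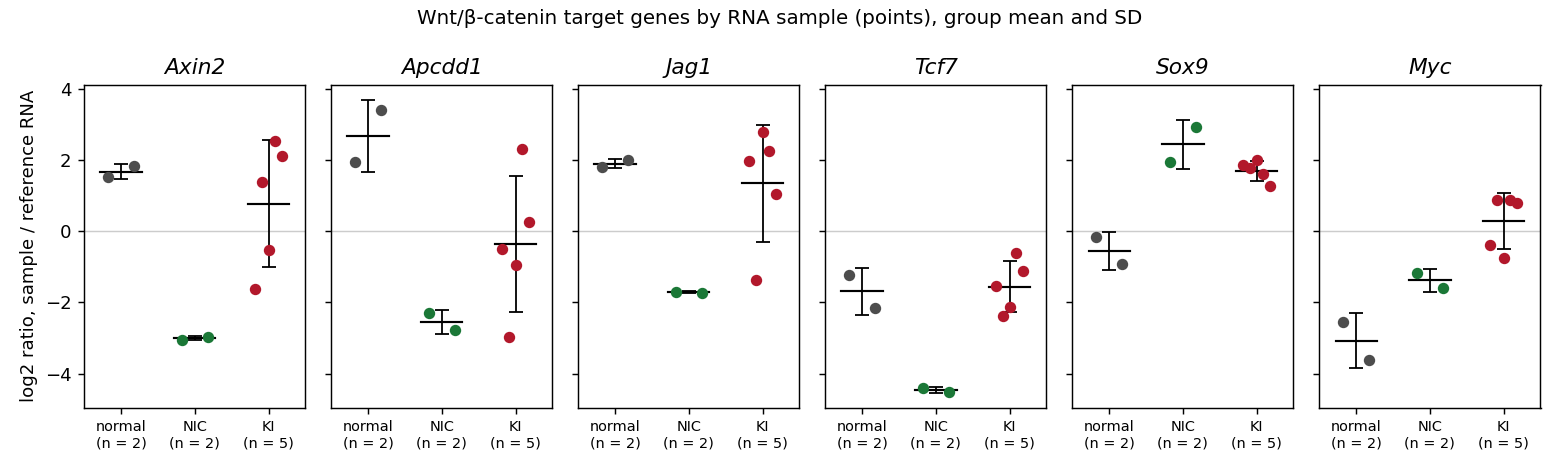
Log2 ratio of sample over reference RNA (vertical axis) for 6 Wnt/β-catenin target genes in normal glands (n = 2), NIC pools (n = 2) and KI tumours (n = 5); points are RNA samples, horizontal lines group means and bars SDs. Axin2 was between −3.05 and −2.97 in the NIC pools and spread from −1.61 to 2.52 over the KI tumours. Each NIC point is a pool of 5 tumours, so the spread among single NIC tumours is not seen.

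ErbB receptors, ligands and feedback genes rose in 14 and fell in 1 of 25 cases (14 and 2 adjusted over the list alone; camera adjusted p = 0.000234, adjusted p = 0.213 with an estimated correlation). The ligand gene Hbegf rose by 3.96 ± 0.64, Etv5 by 3.93 ± 0.30, Etv4 by 2.80 ± 0.35 and Dusp6 by 2.32 ± 0.28. Erbb2 neighbours rose in 9 and fell in 1 of 25 cases (9 and 1 adjusted over the list alone; camera adjusted p = 0.000200, adjusted p = 0.213 with an estimated correlation). Besides Stard3 and Pgap3 these included Top2a (3.59 ± 0.21, its other probe 0.043) and Grb7 (3.33 ± 0.24), whose probe was saturated on 4 of the 10 KI arrays.

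Proliferation genes rose in 28 of 29 cases and fell in 0 (28 adjusted over the list alone; camera adjusted p = 1.31e-13, adjusted p = 0.215 with an estimated correlation). Aurkb rose by 3.38 ± 0.45, the spindle checkpoint gene Bub1 by 3.36 ± 0.47 and Melk by 2.97 ± 0.24. Tight and adherens junction genes rose in 19 of 24 cases and fell in 0 (19 adjusted over the list alone; camera adjusted p = 3.54e-09). This was the list that held its call with an estimated correlation (adjusted p = 0.00963). Ocln rose by 3.53 ± 0.27, Cldn1 by 3.31 ± 0.25, Esrp1 by 3.11 ± 0.16 (its other probe differed by −0.16) and Cldn4 by 2.98 ± 0.49. Cdh1 was 1.47-fold higher (0.56 ± 0.12, adjusted p = 0.00937). It lost its call in 6 of 23 alternatives, 1 of them without normal gland 1, and ran from 0.062 with the Cy3-labelled samples alone to 1.71 with scaling to 1 spread (adjusted p up to 0.733). Luminal epithelium genes rose in 15 and fell in 1 of 24 cases (15 and 1 adjusted over the list alone; camera adjusted p = 0.000133, adjusted p = 0.215 with an estimated correlation). Epcam rose by 3.37 ± 0.33 and Elf3, an epithelial ETS factor, by 3.21 ± 0.24, and Foxa1 fell (−3.91 ± 0.20). Basal and myoepithelial genes went both ways, 7 up and 8 down among 20 (7 and 8 adjusted over the list alone; camera adjusted p = 0.771, upward, with a median of −0.21 and a mean of 0.10). The keratin gene Krt6a rose by 1.86 ± 0.56 and Lgals7 by 4.17 ± 0.30 (its other probe differed by −1.38). Snai2 and Myh11 fell (−2.53 ± 0.73 and −2.14 ± 0.37). Milk proteins and lactation genes rose in 3 and fell in 2 of 17 cases (3 and 2 adjusted over the list alone; camera adjusted p = 0.627). Lalba rose by 2.16 ± 0.67 and Mfge8, a milk fat globule protein gene saturated on 7 KI arrays, by 1.16 ± 0.37. The osteopontin gene Spp1 and the κ-casein gene Csn3 were called too, but both were saturated on all 10 KI arrays.

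Adipocyte genes fell in 19 of 26 cases and rose in 0 (20 and 0 adjusted over the list alone; camera adjusted p = 6.37e-09, adjusted p = 0.244 with an estimated correlation). Dgat2 was at −5.32 ± 0.31, Lep at −4.58 ± 0.21 and Pck1, the gluconeogenic enzyme gene, at −4.46 ± 0.40. Brown fat genes fell in 6 of 10 cases and rose in 0 (6 and 0 adjusted over the list alone; camera adjusted p = 0.000831, adjusted p = 0.348 with an estimated correlation). Cox8b was at −4.91 ± 0.32, Ucp1 at −3.77 ± 0.15, Elovl3 at −3.63 ± 0.16 and Cox7a1 at −3.11 ± 0.34. Endothelium genes fell in 8 of 18 cases and rose in 0 (9 and 0 adjusted over the list alone; camera adjusted p = 0.00422, adjusted p = 0.586 with an estimated correlation). Among these were Tek (−2.39 ± 0.47), the lymphatic marker gene Lyve1 (−1.76 ± 0.40), Vwf (−1.51 ± 0.42) and Cldn5 (−1.48 ± 0.26). Fibroblast and matrix genes rose in 1 and fell in 5 of 27 cases (1 and 5 adjusted over the list alone; camera adjusted p = 0.263). Dcn (−3.96 ± 0.57, its other probe −0.22), Pdgfra (−3.34 ± 0.68) and Lum (−2.36 ± 0.61) fell, and the matrix glycoprotein gene Tnc rose by 2.86 ± 0.36 with its 3 probes between −0.33 and 2.86. EMT regulators rose in 5 and fell in 4 of 19 cases (5 and 4 adjusted over the list alone; camera adjusted p = 0.995, upward, with a median of −0.31 and a mean of −0.14). Sox4 and Tgfb2 rose by 2.63 ± 0.28 and 2.55 ± 0.45, and Twist2 fell (−2.73 ± 0.32).

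B and T lymphocyte genes fell in 16 and rose in 1 of 23 cases (16 and 2 adjusted over the list alone; camera adjusted p = 0.000361, adjusted p = 0.435 with an estimated correlation). Cd79b was at −3.35 ± 0.10, Cxcl13 at −3.08 ± 0.86, Jchain at −3.04 ± 0.38 and Ms4a1 at −2.63 ± 0.42. Myeloid and macrophage genes rose in 4 and fell in 2 of 23 cases (3 and 2 adjusted over the list alone; camera adjusted p = 0.411). S100a8, an abundant protein of neutrophils, rose by 4.47 ± 0.95, Arg1 by 2.66 ± 0.84, the endotoxin coreceptor gene Cd14 by 2.04 ± 0.30 and C1qa by 1.82 ± 0.26. Interferon response genes rose in 5 and fell in 0 of 27 cases (5 and 0 adjusted over the list alone; camera adjusted p = 0.0248, adjusted p = 0.880 with an estimated correlation). Irf7 rose by 4.04 ± 0.71, Isg15 by 3.46 ± 0.94, and the antiviral enzyme genes Oas2 and Oas1a by 3.41 ± 0.87 and 2.34 ± 0.46. Hypoxia and glycolysis genes rose in 5 and fell in 2 of 21 cases (5 and 2 adjusted over the list alone; camera adjusted p = 0.288). The enolase gene Eno1 rose by 2.96 ± 0.79 (its other probe 0.066; 1.51 and not called without normal gland 2, 4.42 without gland 1), Ero1a by 2.81 ± 0.63 and Slc2a1 by 2.38 ± 0.56, and Pfkfb3 fell (−2.71 ± 0.58). Skeletal muscle genes rose in 1 and fell in 3 of 17 cases (1 and 2 adjusted over the list alone; camera adjusted p = 0.742). The calcium pump gene Atp2a1 rose by 1.11 ± 0.31 (its other probe −0.81). Falls were seen for Eno3 (−2.08 ± 0.50; −0.97 without normal gland 2 and −3.20 without gland 1), Acta1 (−1.29 ± 0.41; −0.64 and not called without gland 2, −1.94 without gland 1) and Myh1 (−0.33 ± 0.082). Peripheral nerve genes rose in 4 and fell in 2 of 10 cases (4 and 2 adjusted over the list alone; camera adjusted p = 0.394). Ncmap and Sox10 rose by 2.69 ± 0.39 and 1.25 ± 0.31, and the myelin gene Pmp22 fell (−2.68 ± 0.45).

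The largest rises of single genes were those of S100a8, the interleukin-1 coreceptor gene Il1rap (4.37 ± 0.30), Cwh43 (4.29 ± 0.69), the focal adhesion gene Tes (4.26 ± 1.08), the kinase gene Dyrk3 (4.24 ± 0.33), Lgals7, the Hippo pathway gene Wwc1 (4.09 ± 0.48), Stard3, Ier3 (4.05 ± 0.46) and Irf7. The largest falls were those of Rbp4 (−7.21 ± 0.38), Cd36, Gys2 (−6.0 ± 0.16), the carboxylesterase gene Ces1d (−5.86 ± 0.46), Slc2a5 (−5.53 ± 0.15), Arxes2 (−5.43 ± 0.32), Cyp2e1 (−5.33 ± 0.23), Dgat2, Plin4 (−5.29 ± 0.28) and the iron oxidase gene Heph (−5.27 ± 0.34). Slc2a5 was well above background on 5 and Cyp2e1 on 6 of the 10 KI arrays. Ratios in the KI tumours were −0.061 to −0.023 for Slc2a5 and lay between −0.173 and 0.345 for Gys2, Lep, Ucp1 and Elovl3. A ratio near 0 may give only a bound where signal is dim, so the sizes of these falls are uncertain. Probes of Ocln (−0.46), Tes (−0.53), Pdgfra (0.031) and Myh1 (0.084) went the other way from the probe used. Probes of Vwf (0.075), also the other way, Sox10 (0.087), Pmp22 (−0.15), Lyve1 (−0.22), Sox9 (0.24), Pfkfb3 (−0.26), Il1rap (0.29), Melk (0.33), Etv5 (0.65), Oas2 (0.83), Cd44 (0.83) and Heph (−0.87) differed by less than 1 log2 unit. Table, platform record and KI group cannot be told apart, and the column SDs of the tables did not overlap. Interquartile ranges of the normal and KI columns did not overlap either. Of the 93 called genes named here, 67 kept their call and direction in every alternative. Without normal gland 1 the Wnt/β-catenin target list held 6 called genes, and with quantile normalization 7.

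Both tumour kinds were set against the same 2 glands. Of the genes called, 1924 were higher in both comparisons and 2131 lower in both, against 453 and 705 for independent lists of those sizes. 16 genes were called in opposite directions. The log2 differences correlated across genes at r = 0.832, with a covariance of 0.686. In the mean of 50 simulations without differences between groups these were 0.599 and 0.0563. The simulations drew every sample, glands included, with 1 spread per gene pooled over the groups. A spread between glands that differs from that of the tumours was therefore not modelled. The 2 glands are too few to give each comparison its own 2, so part of the likeness may come from the shared glands.

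KI tumours were compared with NIC pools, again across the 2 tables, so that table, platform record and tumour kind cannot be told apart. Krt14, a keratin of basal cells, was 7.22-fold higher in the KI tumours (log2 difference 2.85 ± 0.23 SE, n = 5 and 2, adjusted p = 0.00237), and Tnc was 8.76-fold higher (3.13 ± 0.36, adjusted p = 0.00541), with its 3 probes between 0.14 and 3.13. The growth factor gene Egf was 10.2-fold lower (−3.35 ± 0.35, adjusted p = 0.0041), and Tfap2b, encoding the transcription factor AP-2β, 14.7-fold lower (−3.88 ± 0.11, adjusted p = 4.16e-05; its other probe differed by −0.86). Tfap2b ratios in the KI tumours lay between −0.128 and 0.249, and a ratio near 0 may give only a bound where signal is dim. Of 28919 genes 1792 were called, 843 higher and 949 lower in KI tumours. Of the 770 that differed at least 2-fold, 306 were higher and 464 lower. Among genes above the median signal on the KI arrays, a filter that favours genes bright in KI tumours, 464 were called higher and 419 lower.

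Axin2 was 3.78 ± 1.09 higher in the KI tumours and did not pass the threshold (adjusted p = 0.0899), though each of the 5 KI tumours lay above both NIC pools. Its lowest adjusted p, 0.00422, came from the limma fit of all arrays with the RNA sample as a random block. That fit takes 1 correlation between paired arrays for all genes. Paired arrays of a gene that varies mainly between tumours may then partly count as replicates. The next lowest adjusted p of Axin2 was 0.0287, with KI values from the scanner files. It was 0.0382 without KI tumour 1, the lowest of the 5, and 0.0942 to 0.162 without each other KI tumour. The difference was 3.74 without NIC pool 1 and 3.82 without pool 2. Of the 31 Wnt/β-catenin targets and feedback genes 1 rose, 1 fell and 29 did not pass the test (1 and 1 adjusted over the list alone). Tcf7, a transcription factor that partners β-catenin, rose by 2.91 ± 0.49 (adjusted p = 0.0185; its other probe differed by 1.22), and Fgf9 fell (−0.37 ± 0.074). As a list they were called upward (camera adjusted p = 0.0467, adjusted p = 0.907 with an estimated correlation). In the same samples the median difference was 0.75 for the fibroblast list, −0.087 for the adipocyte list and −0.048 for the endothelium list. Every list that camera called in this comparison lost its call in the same way, with the same adjusted p = 0.907 with an estimated correlation. Wnt pathway components rose in 1 and fell in 2 of 37 cases (2 and 2 adjusted over the list alone; camera adjusted p = 0.529). Wnt10b rose by 0.30, and Lrp5 and Fzd8 fell (−1.11 ± 0.23 and −0.34). Ctnnb1 and Cdh1 did not differ beyond the spread (0.35 ± 0.41, adjusted p = 0.692, and 0.040 ± 0.12, adjusted p = 0.895). The other 2 Ctnnb1 probes differed by 0.285 and −0.52, and the probe used ran from 0.12 without KI tumour 3 to 0.54 without KI tumour 2. With KI values from the scanner files Cdh1 turned to −0.39 (adjusted p = 0.041), and with scaling to 1 spread it was 0.89 higher (adjusted p = 0.0153; up to 0.996 over the alternatives).

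The Erbb2 probe used showed no difference between the tumour kinds (0.13 ± 0.20, adjusted p = 0.772; −0.082 without NIC pool 1 and 0.34 without pool 2), while the other 2 probes differed by 1.76 and −0.033. Erbb2 neighbours rose in 3 and fell in 0 of 25 cases (3 and 0 adjusted over the list alone; camera adjusted p = 0.00398, adjusted p = 0.907 with an estimated correlation). They were Pgap3, which takes part in the remodelling of lipid anchors (2.39 ± 0.54), Mien1 (1.37 ± 0.23) and Grb7 (1.31 ± 0.24). Mien1 and Grb7 were saturated on 5 and 4 of the 10 KI arrays, where saturation holds the measured level down. ErbB receptors, ligands and feedback genes rose in 0 and fell in 1 of 25 cases, Egf (0 and 1 adjusted over the list alone; camera adjusted p = 0.829).

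**Figure D3:**
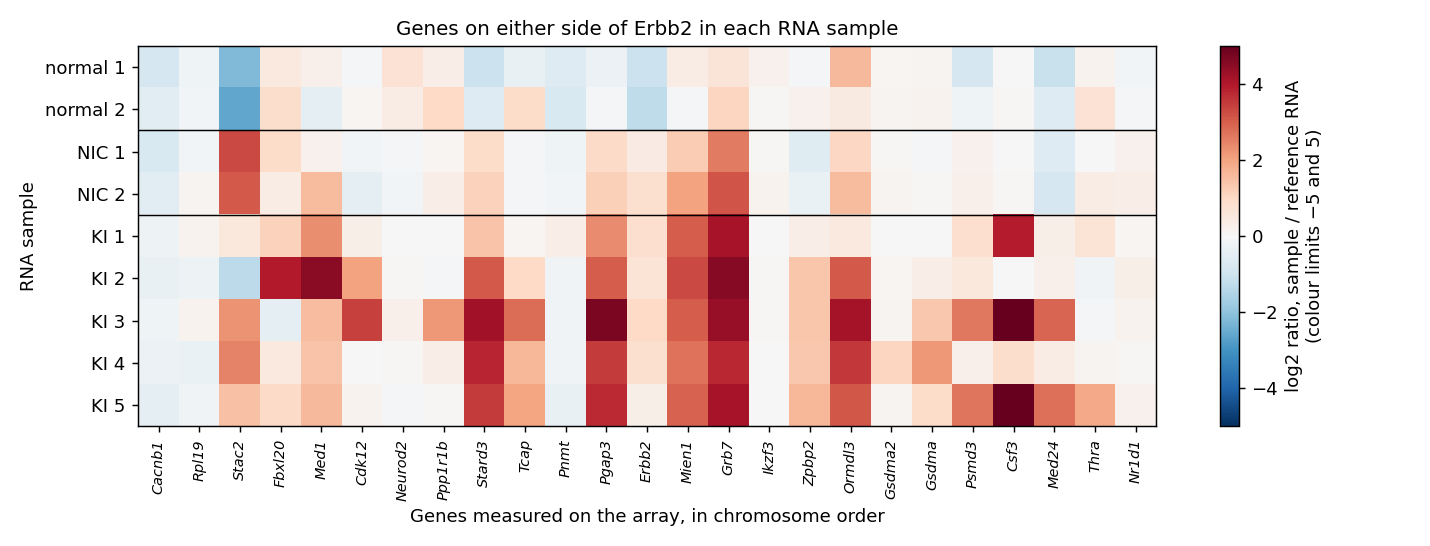
Heatmap of log2 ratios of sample over reference RNA (colour, limits −5 and 5) for Erbb2 and the 12 measured genes on each side of it in chromosome order (horizontal axis) in the 9 RNA samples (vertical axis; lines part normal, NIC and KI). Grb7 was at 3.76 to 4.56 in the KI tumours, 2.62 and 3.13 in the NIC pools and 0.64 and 1.06 in the normal glands.

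EMT regulators rose in 3 and fell in 0 of 19 cases (3 and 0 adjusted over the list alone; camera adjusted p = 0.00228, adjusted p = 0.907 with an estimated correlation). The gelatinase gene Mmp9 rose by 2.00 ± 0.22, and the transcription factor genes Foxc2 and Zeb2 by 1.14 ± 0.14 and 0.80 ± 0.12. Fibroblast and matrix genes rose in 1 and fell in 0 of 27 cases (1 and 0 adjusted over the list alone; camera adjusted p = 0.00228, adjusted p = 0.907 with an estimated correlation). Tnc was the called gene, and 26 of the 27 had a higher mean in KI tumours. Basal and myoepithelial genes rose in 1 and fell in 0 of 20 cases, Krt14 (1 and 0 adjusted over the list alone; camera adjusted p = 0.0275, adjusted p = 0.907 with an estimated correlation). Luminal epithelium genes rose in 2 and fell in 3 of 24 cases (2 and 3 adjusted over the list alone; camera adjusted p = 0.341, downward, with a median of −0.21 and a mean of 0.081). Krt19, a simple-epithelium keratin, rose by 3.19 ± 0.64 and Elf3 by 1.28 ± 0.24, and Foxa1 and the prolactin receptor gene Prlr fell (−0.87 ± 0.20 and −0.85 ± 0.12), Foxa1 by −0.51 and not called without NIC pool 2. Tight and adherens junction genes rose in 1 and fell in 1 of 24 cases (1 and 3 adjusted over the list alone; camera adjusted p = 0.873, downward, with a median of 0.0050 and a mean of 0.057). The plakophilin gene Pkp1 rose by 1.98 ± 0.40 (1.29 and not called without NIC pool 1) and the desmocollin gene Dsc2 fell (−1.35 ± 0.17). Milk proteins and lactation genes held no called member among 17 (0 and 0 adjusted over the list alone; camera adjusted p = 0.916). Glycam1 and Csn1s2a had the largest differences, 3.03 ± 1.12 and −1.22 ± 0.79, and were saturated on 1 and 6 of the 10 KI arrays, which holds the KI level down. Proliferation genes rose in 1 and fell in 0 of 29 cases (0 and 0 adjusted over the list alone; camera adjusted p = 0.916, upward, with a median of −0.0029 and a mean of −0.0048). The survival gene Birc5 rose by 0.52 ± 0.12.

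Myeloid and macrophage genes rose in 2 and fell in 0 of 23 cases (2 and 0 adjusted over the list alone; camera adjusted p = 0.0467, adjusted p = 0.907 with an estimated correlation). S100a8 rose by 4.19 ± 0.95 and Cd14 by 1.72 ± 0.30. B and T lymphocyte genes rose in 2 and fell in 0 of 23 cases (2 and 1 adjusted over the list alone; camera adjusted p = 0.344). Cd5 rose by 0.72 ± 0.13 and Cd79b by 0.48 ± 0.10, and Cd79b turned to −0.0045 with quantile normalization. Hypoxia and glycolysis genes rose in 1 and fell in 1 of 21 cases (1 and 1 adjusted over the list alone; camera adjusted p = 0.0467 downward, adjusted p = 0.907 with an estimated correlation). Ndrg1 rose by 1.53 ± 0.29 and the carbonic anhydrase gene Car9 fell (−0.97 ± 0.21). Brown fat genes rose in 0 and fell in 3 of 10 cases (0 and 3 adjusted over the list alone; camera adjusted p = 0.344, downward, with a median of 0.070 and a mean of −0.41). They were Cox8b (−3.05 ± 0.32), Cox7a1 (−2.11 ± 0.34) and Ppargc1a (−0.79 ± 0.15). Adipocyte genes rose in 1 and fell in 0 of 26 cases (0 and 0 adjusted over the list alone; camera adjusted p = 0.529), Slc2a4 by 1.07 ± 0.25. Skeletal muscle genes rose in 1 and fell in 0 of 17 (2 and 0 adjusted over the list alone; camera adjusted p = 0.147), Des by 1.69 ± 0.28. No member was called among 18 endothelium genes (0 and 0 adjusted over the list alone; camera adjusted p = 0.893, upward, with a median of −0.048 and a mean of 0.17), 27 interferon response genes (0 and 0 adjusted over the list alone; camera adjusted p = 0.344) or 10 peripheral nerve genes (0 and 0 adjusted over the list alone; camera adjusted p = 0.796). Their largest differences were those of Eng and Flt1 (0.99 ± 0.33 and 0.98 ± 0.45), Cxcl10 and Oas2 (2.46 ± 1.43 and 1.97 ± 0.87; Oas2 1.16 without NIC pool 2), and S100b and Sox10 (−1.35 ± 0.71 and −0.96 ± 0.31).

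The largest rises of single genes were those of Cyp1b1, a steroid-metabolizing enzyme (4.40 ± 1.03), S100a8, Nfe2l3 (4.12 ± 0.27, its other probe −0.071), Pdk4 (4.10 ± 0.93), Apobr (4.07 ± 0.55), the prostaglandin receptor gene Ptger2 (3.90 ± 0.54), Gvin1 (3.81 ± 0.77), Rerg (3.64 ± 0.47), the small heat shock protein gene Hspb8 (3.64 ± 0.43) and the proprotein convertase gene Pcsk6 (3.49 ± 0.49). The largest falls were those of the GABA receptor gene Gabra4 (−3.96 ± 0.13), Tfap2b, the pyrimidine-degrading enzyme gene Dpyd (−3.85 ± 0.38), the tetraspanin gene Tspan8 (−3.78 ± 0.44), Luzp2 (−3.60 ± 0.27, its other probe −0.11), Tmigd1 (−3.46 ± 0.42), the angiotensinogen gene Agt (−3.38 ± 0.51), Egf, Cabcoco1 (−3.33 ± 0.24, well above background on 6 KI arrays) and Tesc (−3.32 ± 0.72, its other probe −0.050). In the KI tumours ratios lay between −0.097 and 0.252 for Gabra4, −0.128 and 0.249 for Tfap2b, and −0.072 and 0.004 for Luzp2. Ratios near 0 may give only a bound where signal is dim, so the sizes of these falls are uncertain. Such ratios also vary little between tumours, which may help these genes keep a call in the alternatives. Other probes of Cyp1b1 (0.64), Gvin1 (0.75), Oas2 (0.49), Sox10 (−0.53) and Zeb2 (0.18) differed by less than 1 log2 unit, and those of Fzd8 (0.084) and Flt1 (−0.07) went the other way. Of the 50 called genes named in this comparison, 14 kept their call and direction in every alternative: Gabra4, Tfap2b, Dpyd, Tspan8, Luzp2, Tmigd1, Egf, Cabcoco1, Cox8b, Nfe2l3, Hspb8, Krt14, Tnc and Mmp9. Without NIC pool 1 the count was 503, without NIC pool 2 591 and without KI tumour 5 869, and the Wnt/β-catenin target list held 0 called genes without either NIC pool (6 and 5 at an unadjusted p under 0.05), 7 without KI tumour 2 and 1 without KI tumour 4 or 5. Quantile normalization gave 356 higher and 729 lower, scaling to 1 spread 358 and 591, and KI values from the scanner files 2002 and 1706.

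Single KI tumours differed from one another. In the scanner values 710 genes, 2.46% of 28919, had a range over 2 log2 units between the 5 tumours that also exceeded 3 times the difference between paired arrays. The largest ranges were those of Cav2, a caveolin (4.32 in tumour 1 and −1.66 to −0.92 in the others), and Ifi27l2a, an interferon-induced gene (4.12 in tumour 3 and −1.77 to 0.66 in the others). The neutrophil chemokine gene Cxcl5 (1.74), the placental hormone genes Prl2c3 (2.82) and Prl2c5 (2.79), Bst1 (3.27) and the stefin genes Cstdc6 (4.94) and Stfa2l1 (4.62) were highest in tumour 1. The amino acid transporter gene Slc6a15 was highest in tumour 4 (3.92), and Csf3, the neutrophil growth factor gene, in tumour 3 (4.72) and tumour 5 (4.2). Without tumour 2 the count was 374, without tumour 1 463, and 1130 genes had such a range in the deposited values.

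Lists differed in how many members had such a range: 21 of 27 interferon response genes, 9 of 31 Wnt/β-catenin targets (Axin2, Lef1, Nkd2, Rnf43, Apcdd1, Cd44, Jag1, Fst and Tnfrsf19), and 9 of 25 Erbb2 neighbours, against 0 of 29 proliferation and 0 of 18 endothelium genes. Fisher's exact test against all genes, chosen after these counts were seen, gave adjusted p = 5.99e-28, 2.55e-07 and 4.43e-08 for those 3 lists, over 20 lists of genes that are not independent. Lists with similar shares were 7 of 21 hypoxia (adjusted p = 2.25e-06), 7 of 26 adipocyte (9.14e-06), 6 of 19 EMT (1.48e-05), 6 of 23 myeloid (4.33e-05) and 5 of 17 milk genes (0.000106). Also under the threshold were 5 of 27 fibroblast (0.00101), 3 of 20 basal (0.0246) and 2 of 10 nerve genes (0.0432). The remaining counts were 3 of 37 Wnt pathway, 2 of 25 ErbB, 2 of 17 muscle, and 1 each of 24 luminal, 24 junction, 23 lymphocyte and 10 brown fat genes. In the value table the interferon list's median was 2.57 in tumour 3, 1.66 in tumour 1, 0.69 in tumour 4, and 0.38 and 0.39 in tumours 2 and 5.

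Around Cav2 on its chromosome, a region chosen after the values were seen, tumour 1 stood apart in several neighbouring genes. In the value table Tes was at 4.17 in tumour 1 and at 0.34 to 0.84 in the other KI tumours, Cav2 at 4.34 against −1.83 to −0.99, and Cav1, the main caveolin of caveolae, at 1.31 against −2.56 to −1.43. Met, the receptor of hepatocyte growth factor, was at 2.80 against 0.10 to 0.51, Capza2 at 2.34 against 0.020 to 0.54, and St7 at 3.69 against −0.58 to −0.28. Tes and Cav2 were each saturated on 2 of the 10 KI arrays.

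**Figure D4:**
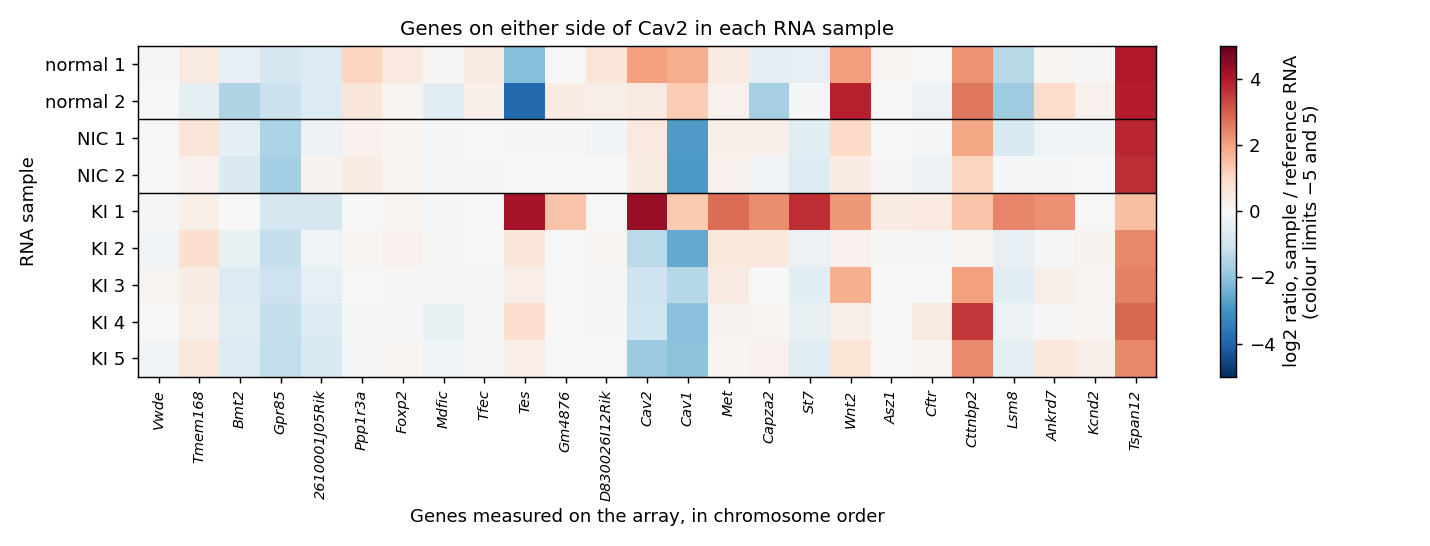
Heatmap of log2 ratios of sample over reference RNA (colour, limits −5 and 5) for Cav2 and the 12 measured genes on each side of it in chromosome order (horizontal axis) in the 9 RNA samples (vertical axis; lines part normal, NIC and KI). Tes, Cav2, Met, Capza2 and St7 were higher in KI tumour 1 than in the other 8 samples.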

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

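The tests of the region around Cav2 were chosen after the results were seen. In the 5 KI tumours, 203 results were tested for 1 tumour standing apart, measured as its gap to the nearest other tumour divided by the whole range; 25 (12.3%) passed the critical value of 0.71, where chance gives about 1 in 20 for independent results. The 203 include genes picked for their range between these tumours and genes and lists that vary together, so part of the excess is built in. Of these, 12 fell on tumour 2 (5 as the highest and 7 as the lowest), 8 on tumour 3, 4 on tumour 1 and 1 on tumour 4.

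Tumour 2 was highest for Myl1 (0.955; 1.32 against −2.60 to −2.42 in the others), Egf (0.824), Esrp1 (0.769), Hsd11b1 (0.728) and the skeletal muscle list (0.755; 0.74 against −0.20 to 0.033). It was lowest for Eng (0.868; −0.49 against 0.59 to 0.75), Krt6a (0.836), Arg1 (0.825; 1.87 against 4.37 to 4.90), Hbegf (0.80), Cwh43 (0.784), Cdh5 (0.713) and the EMT list (0.794; −2.16 against −0.71 to −0.34). Tumour 3 was highest for Gys2 (0.916), Cyp2e1 (0.910), Plin4 (0.842), Oas2 (0.814; 4.26 against 1.30 to 1.85), Oas1a (0.755), Mfge8 (0.739), Ces1d (0.738) and Rbp4 (0.714). Tumour 1 was highest for Prl2c3 (0.907), Prl2c5 (0.899), Cav2 (0.876) and Tes (0.869), and tumour 4 for the Wnt/β-catenin target list (0.718; 0.50 against −0.022 to 0.12).

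The run of genes around Cav2 was high in KI tumour 1, and stromal or fat cells, which express Cav1 and Cav2, would raise their other markers, but tumour 1 lay below the highest other KI tumour in the adipocyte, endothelium and fibroblast lists, with the smallest of the 3 gaps at −0.35. Chance was not excluded: 0.0318% of 18890 runs of 11 consecutive genes had a median deviation as high (2.17), but the region was picked for Cav2, the gene with the largest range, which fixes a small share. Co-regulation of neighbours stays open too, with a run nearly as high over the Oas cluster of co-induced interferon genes in tumour 3 (1.79). Further such runs lay around Timp2 in tumour 2 (1.845) and, in the flank of Erbb2, around Nr1d1 in tumour 5 (1.89). A gain of this chromosome segment is a further hypothesis that may apply, and DNA was not measured.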

How the results depend on the processing

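The scaling to 1 spread and the filter to genes above the median signal on the KI arrays were chosen after seeing the data. The other alternatives were planned. The cause of the changes was not tested. Where a group is left with 1 sample, that sample is assumed to vary like the others.

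For NIC against normal (5377 genes, 12 of them Wnt/β-catenin targets), samples in Cy3 alone gave 2048 (6), all arrays with a dye term and the RNA sample as a random block 9992 (19), all 9 samples in the fit 10395, and genes above the median signal 3430. Leaving out each sample gave 0 to 4236 (0 to 11); the 0 came without either NIC pool, where limma's unadjusted counts were 6400 and 6977 (13 and 12).

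For KI against normal (12349), a minimum difference of 1 gave 4288 (6 Wnt/β-catenin targets), quantile normalization 7 targets, and genes above the median signal 6505. Leaving out each sample gave 9271 to 12069 (6 to 14).

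For KI against NIC (1792), quantile normalization gave 1085, the random block 3582 (9 targets), a minimum difference of 1 gave 770 (1), KI values from the scanner files 3708 (6), scaling to 1 spread 949 (1), and genes above the median signal 883 (1). Leaving out each sample gave 503 to 2101 (0 to 7). The limma count of 0 targets came without either NIC pool, with unadjusted counts of 6 and 5. Genes with a wide range between KI tumours (710) numbered 1130 in the deposited table and 374 to 667 without each tumour.

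Directions reversed for Ctnnb1 in NIC against normal (−0.071 with Cy5 alone). In KI against NIC they reversed for Cd79b (−0.0045 with quantile normalization, −0.10 with 1 spread), for Erbb2 (−0.082 without NIC pool 1; −0.082 to 0.34 leaving out each sample) and for Cdh1 (−0.22 with Cy3 alone, −0.39 from the scanner files, −0.22 from the scanner log ratios, −0.019 without KI tumour 3; −0.019 to 0.080 leaving out each sample). Over named genes and alternatives, NIC against normal kept call and direction in 1234 of 1511 cases, with 276 weaker, 0 stronger and 1 reversed. KI against normal kept 2057 of 2158 (100 weaker, 1 stronger, 0 reversed) and KI against NIC 1158 of 1410 (236, 9 and 7).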

Other observations

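The tests of gene runs, of the range between tumours, of normal gland RNA and of a shift between tables were chosen after the results were seen. Genes beside Erbb2 differed in extent between single KI tumours. Stard3, Pgap3 and Grb7 were above both NIC pools in all 5 KI tumours, but the flanks varied: Fbxl20 and Med1 were highest in tumour 2 (3.96 and 4.51), Cdk12 in tumour 3 (3.40), and Psmd3 and Med24 in tumours 3 (2.65 and 2.92) and 5 (2.69 and 2.76). Csf3 was at 5.36 in tumour 3, 5.13 in tumour 5 and 3.93 in tumour 1, against 0.0090 in tumour 2.

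Of 25 Erbb2 neighbours 21 had a higher mean in KI tumours than in NIC pools, and 3 were called higher. The list's camera call (adjusted p = 0.00398) was lost (adjusted p = 0.907 with an estimated correlation), as was that of every list called in this comparison. The run of 11 genes centred on Erbb2 had a median difference of 1.37, as high in 0.0212% of 18890 runs, which argues against unrelated genes that happen to lie together. A shift between the value tables would not part single KI tumours, which share a table, yet 36% of the listed neighbours had a range over 2 log2 units between them. For the difference from NIC itself, table and platform record cannot be told apart from tumour kind, since 0 pairs of KI and NIC arrays share a table. A segment gain of varying extent may apply as a hypothesis, but DNA was not measured. Erbb2 itself differed by 0.13 (other probes 1.76 and −0.033), Pnmt, Ikzf3 and Neurod2 by 0.055, −0.095 and 0.15, and Stac2 by −2.10. In the tumour samples ratios lay between −0.382 and 0.316 for Pnmt, −0.038 and 0.192 for Ikzf3, and −0.134 and 0.271 for Neurod2. Where a probe is dim, a ratio near 0 could not show a gain, so Pnmt, Ikzf3 and Neurod2 do not decide the question.

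Axin2 was higher in each KI tumour than in both NIC pools. Tumours 1, 2 and 3 (−1.61, 1.375 and −0.53) lay below both normal glands (1.53 and 1.81). Tumours 4 and 5 (2.52 and 2.11) lay above them. The limma test was not passed (adjusted p = 0.0899). An adjusted p of 0.00422 came with all arrays and the RNA sample as a random block, and 0.0382 without KI tumour 1. The random block fit takes 1 correlation between paired arrays for all genes, so its p may be too small here. Without each other KI tumour it was 0.0942 to 0.162. RNA of whole normal gland would need a share of 51.7% for the KI mean, a log2 of −0.95, while the adipocyte list lay at −2.33 (tumours from −3.11 to −1.99, SD 0.41), which allows 19.9%. That share was computed for the mean of the KI tumours and not for each tumour. Tumours 1 and 3, nearest to the NIC level, would need less, so gland RNA is not excluded for them. A shift between tables or platform records stays open, as 0 pairs of KI and NIC arrays share a table. Other cell types stay open as well, since the fibroblast, EMT and basal lists lay higher in KI than in NIC in the median (0.75, 0.89 and 0.43; 26 of 27, 17 of 19 and 16 of 20 genes). A difference in β-catenin signalling may apply as a hypothesis, which was not measured. The target list lost its call with an estimated correlation, as did every list called in this comparison.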
